A study of Mus musculus with 3 samples.

How the data were processed

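Gene expression was measured in total RNA of mouse neural retina with Affymetrix U74Av2 arrays, an early oligonucleotide array on which each probe set is a group of short probes for 1 transcript. Per the labels, all 3 samples came from wild-type mice at postnatal day 18 on a mixed 129/SvEv and C57BL/6 background. They were littermates of mice without Rp1, a photoreceptor microtubule protein, and those mutants were not analysed here. Each RNA was a pool from 3 to 4 mice, and collection was in the early afternoon. The samples are called pools 1, 2 and 3, and the numbers are only names. The labels do not state that the pools held different animals, so the spread between these samples may be partly technical. The p-values for single genes rest on this spread pooled over genes. Those for gene lists compare genes with other genes and hold no error between animals.

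The deposited values were linear probe set intensities, already scaled before deposit: after the lowest and highest 2% of values were left out, the mean was 500.3 on each of the 3 arrays. The tool and settings behind these values are not given in the sources used here. Each array held 12488 probe sets, of which 66 were manufacturer controls and were used only to describe the arrays and for an alternative level. Signals ran from 1.1 to 46586.7 in pool 1, from 1.7 to 66836.3 in pool 2 and from 0.9 to 54699.3 in pool 3. Gene names came from the array's annotation table, with symbols updated through Entrez identifiers to the RefSeq annotation of GRCm38.p6 for 10817 probe sets and kept as given for 16. Of the probe sets that are not controls, 10833 named 1 gene, 396 named several genes and 1193 were unnamed in that table. Only the first kind was used for genes, which gave 8251 genes. Where a gene had several probe sets, as 2073 genes did, the probe set with the highest mean log2 signal stood for it. No coordinates are given, because no genome build is named for the array.

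Signals were put on the log2 scale, the medians of the 3 arrays were set equal, and values under the 10th percentile of an array were raised to that percentile. Printed signals are these scaled values on the linear scale, except those of array controls and whole arrays, which are as deposited. No detection calls were used. Instead, a level was set on each array at the 90th percentile over 47 measured genes of liver, testis and lymphocytes, here called the off-tissue level. It lay at 241 signal units in pool 1, 219 in pool 2 and 347 in pool 3. By its construction a few of those genes exceed it, and the testis gene Tnp1 was the 1 of 47 called above it. Because probe sets differ in brightness, a call above the level sets a gene against the probe sets of other genes and does not measure an amount, and 2 named genes are not ranked by signal.

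Signal above this level was tested per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, one-sided, Benjamini-Hochberg adjustment over the 8251 genes, threshold 0.05). limma's prior degrees of freedom came out as infinite, so the error of a gene followed the trend of variance with signal and not the gene's own 3 values. The uncertainty of the level itself is not part of that test. Before the data were examined, 28 gene lists with 452 genes had been written for retinal cell classes, neighbouring tissues, cell states and the off-tissue genes. Of these genes 343 were measured, and none was in more than 1 list. For the 25 lists that did not set the level, members above the level were compared with all other genes by a two-sided Fisher's exact test.

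For the spread between pools, only the 4523 genes with a mean above the mean level were used. Each list with 3 or more such members was compared with 10000 random lists of the same size, matched in 20 bins of mean signal. The measures were the median SD of its members and, per pool, the median log2 deviation of its members from the mean of the other 2 pools. There were 23 lists for the first measure and 69 tests of a list in a pool for the second, and both families were adjusted with the Benjamini-Hochberg method. These two-sided permutation p-values describe the 3 arrays, since genes are not replicates, and the smallest that they can give is 2e-04. The 3 deviations of a gene sum to 0 over the pools, so a rise in 1 pool lowers the values of the others.

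The named genes followed a rule fixed beforehand: Rp1, the first 4 measured genes of each photoreceptor, retinoid and retinal cell class list, the first 2 of every other list, the 20 genes with the widest range over the pools, and the 4 widest members of each list whose spread or shift passed the test. Other members are named here as examples chosen after their values were seen. No probe set named Rp1 in the annotation table, so it is not reported.

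The procedures were tested on simulated data with the means of the real genes, each with the spread of a random gene of similar signal. Noise was drawn independently for each gene. False calls for lists whose members vary together were therefore not measured. limma called 82% of 200 genes placed 1 log2 unit above the level, 95% of 200 placed 2 units above it and 0.5% of 200 placed 1 unit below it, in a run of 8251 genes. Among 4617 genes, the shift test called 70% of 10 lists shifted by 0.5 and 100% of 10 lists shifted by 1, and 0% of 60 tests of unshifted lists. The spread test called 0% of the lists shifted by 0.5, 30% of those shifted by 1 and 0% of 20 unshifted lists, so it misses most shifts of this size. A first simulation, in which 100 of the lists were shifted by 0.5 at once among 4605 genes and noise was pooled per signal bin, had recovered 1% by shift and 0% by spread. It was the simulation that was then revised, not the tests.

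The alternatives changed the scaling (values as deposited, or quantile normalization), the floor, the off-tissue level (75th or 95th percentile, or unspiked bacterial controls), the filter on dim genes, the value per gene, the probe sets used, the bins, the fold counted, the test, and each pool left out. A single level for all arrays and another variance in limma (no trend, or no pooling over genes) were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.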

Results

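The series holds 3 arrays of neural retina from wild-type mice at postnatal day 18, in a single group, so no comparison between groups could be made. The labels give these mice as littermates of Rp1-null animals. The measurements answer which genes and cell classes gave signal in the retina at this age, and how far the 3 pools differed. Before scaling, the median deposited signal without control probe sets was 228 in pool 1, 234 in pool 2 and 229 in pool 3. These medians were then set equal. The number of arrays limits the precision of every value. Errors are SDs over the 3 pools.

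Of the 13 measured rod phototransduction genes, 11 were above the level set by liver, testis and lymphocyte genes. Gnat1, the rod transducin alpha subunit, had a signal of 43574 ± 9730.0 (SD, n = 3). The rod phosphodiesterase genes Pde6b at 13979.8 ± 1494, Pde6g at 28046 ± 1631 and Pde6a at 2437 ± 281 were above it as well. The members that were not called were Gucy2e at 401 ± 175 and Rgs9 at 92.4 ± 37.5. The cone list had 4 of 8 members above, namely the cone opsins Opn1sw (3162 ± 816) and Opn1mw (1842 ± 609), the cone transducin gene Gnat2 (2421 ± 334) and Gnb3 (3802 ± 162). The cone channel gene Cnga3 was at 32.9 ± 13.0, below the level on each array.

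Genes that build or regulate photoreceptors were examined in 3 further lists. In the outer segment and cilium list 7 of 8 members were above the level, among them the disc rim genes Prph2 (4733 ± 3514) and Rom1 (6008 ± 329) and the cilium-associated gene Tulp1 (14042 ± 1074), while Rpgr was at 384 ± 137. The signals of Prph2 were 3326, 8732 and 2140 in pools 1 to 3. Among photoreceptor transcription factors 5 of 8 were above, including Crx (6301 ± 569), Nrl (773 ± 58.4) and Neurod1 (4129 ± 792). Prdm1 was not called, at 277 ± 82.0. Of the 5 measured retinoid cycle genes, Rlbp1 (4273 ± 603), which encodes the retinaldehyde-binding protein of Müller glia and pigment epithelium, and Rdh11 (1595 ± 383) were above. The pigment epithelium genes Rdh5 and Rgr were not, with means of 267 ± 331 and 264 ± 149.

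Of 11 Müller glia genes 10 were above the level, with the glutamine synthetase gene Glul at 2209 ± 565, Clu at 4999 ± 1048, Apoe at 8319.8 ± 1993 and the water channel gene Aqp4 at 1247 ± 309, and Vim was not. The ganglion cell list had 10 of 12 above, including Thy1 (2398 ± 698), Sncg (1307 ± 146) and the neurofilament genes Nefl (1453 ± 179.8) and Nefm (478 ± 194). The bipolar list had 7 of 8 above, with Pcp2 at 2163 ± 239, Prkca at 462 ± 49.1 and Car8 at 568 ± 137, while the ON bipolar channel gene Trpm1 was at 410.1 ± 117. Amacrine and horizontal cell genes were above in 10 of 19 cases, among them the GABA synthesis gene Gad1 (4909 ± 814), Calb1 (994 ± 218) and the glycine transporter gene Slc6a9 (2707 ± 493), while Lhx1 was at 185 ± 126.

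Lists of other cells and tissues were counted in the same way. Astrocyte and gliosis genes were above in 4 of 15 cases, microglia genes in 4 of 16 and vascular genes in 3 of 14. The astrocyte filament gene Gfap (373 ± 59.5), S100b (191 ± 58.0), C1qa (325 ± 97.7), Csf1r (320.4 ± 7.55) and Pecam1 (284 ± 27.3) were not called, and the endothelial receptor gene Kdr was, at 575 ± 131. Cornea and sclera genes were above in 3 of 13 cases, skeletal muscle genes in 2 of 13, cell division genes in 3 of 16 and MHC genes in 2 of 9. Krt12, Ckm, Acta1, Mki67 and Top2a were not called above the level, and Col1a1, H2-K1 and H2-D1 were. Pvalb and Casq1 were the 2 skeletal muscle genes. The lens list had 10 of 12 members above, and the erythroid list 3 of 6, which were the haemoglobin genes Hba-a1 and Hbb-b2 and the haem synthesis gene Alas2. The pigment list had 3 of 7 above.

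Of 15 glycolysis genes 14 were above the level, with Hk2 at 2489.8 ± 412 and Pkm at 19199.9 ± 3912. Heat shock and stress genes were above in 15 of 17 cases, with the inducible Hsp70 genes Hspa1a at 843 ± 375 and Hspa1b at 595 ± 151. Oxidative phosphorylation genes were above in 13 of 18 cases, Cox4i1 among them and Cox5a not. Daily rhythm genes were above in 11 of 14 cases, including Dbp (1229 ± 48.5) and Per1 (487 ± 187). Immediate early genes were above in 7 of 15 cases, with Fos called at 472 ± 157 and Egr1 not called at 454 ± 387. Of 4 sex chromosome genes only Eif2s3y was called.

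Over all genes, 3593 of 8251 (43.5%) were above the level at an adjusted p under 0.05 in limma. Compared with this share, 7 of the 25 lists had more members above and 0 had fewer by Fisher's exact test. The adjusted p of the exact test was 0.00194 for glycolysis, 0.003 for heat shock and stress, 0.0135 for Müller glia, 0.0224 for rod phototransduction, 0.0289 for both ganglion cells and lens, and 0.0442 for daily rhythm genes. Oxidative phosphorylation (adjusted p = 0.0526), outer segment and cilium and bipolar cells (both 0.0624) failed the correction in that test. When each list's median signal was instead set against random lists not matched on signal, 8 lists were higher and 0 lower. Outer segment and cilium and oxidative phosphorylation were then called (both adjusted permutation p = 0.001), and daily rhythm was not (adjusted permutation p = 0.131). Skeletal muscle (0.112) and cell division (0.154) had the lowest adjusted p among lists with fewer members above, and skeletal muscle was the 1 list of this kind with an unadjusted exact p under 0.05 (0.0494). Adjusted over the list alone, the count of members above changed to 8 of 8 for bipolar cells, 11 of 12 for lens, 16 of 17 for heat shock and 1 of 16 for microglia, and was equal for the other lists. The number of lists with more members above rests on where the level is set: it was 1 with the 75th percentile and 0 with bacterial controls, under which 5703 genes were above. Calls were also compared over 15 alternatives that kept the exact test. The call was lost in 11 for daily rhythm, 9 for ganglion cells, 6 for lens and 4 for Müller glia. It was lost in 3 for heat shock and stress, 2 for rod phototransduction and 1 for glycolysis. A call was gained in 6 for both outer segment and cilium and bipolar cells, and in 2 for oxidative phosphorylation. A call of fewer members was gained in 2 each for microglia and MHC genes and in 1 each for cornea and sclera and cell division. Prph2 was not called when limma did not pool the variance over genes.

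**Figure D1:**
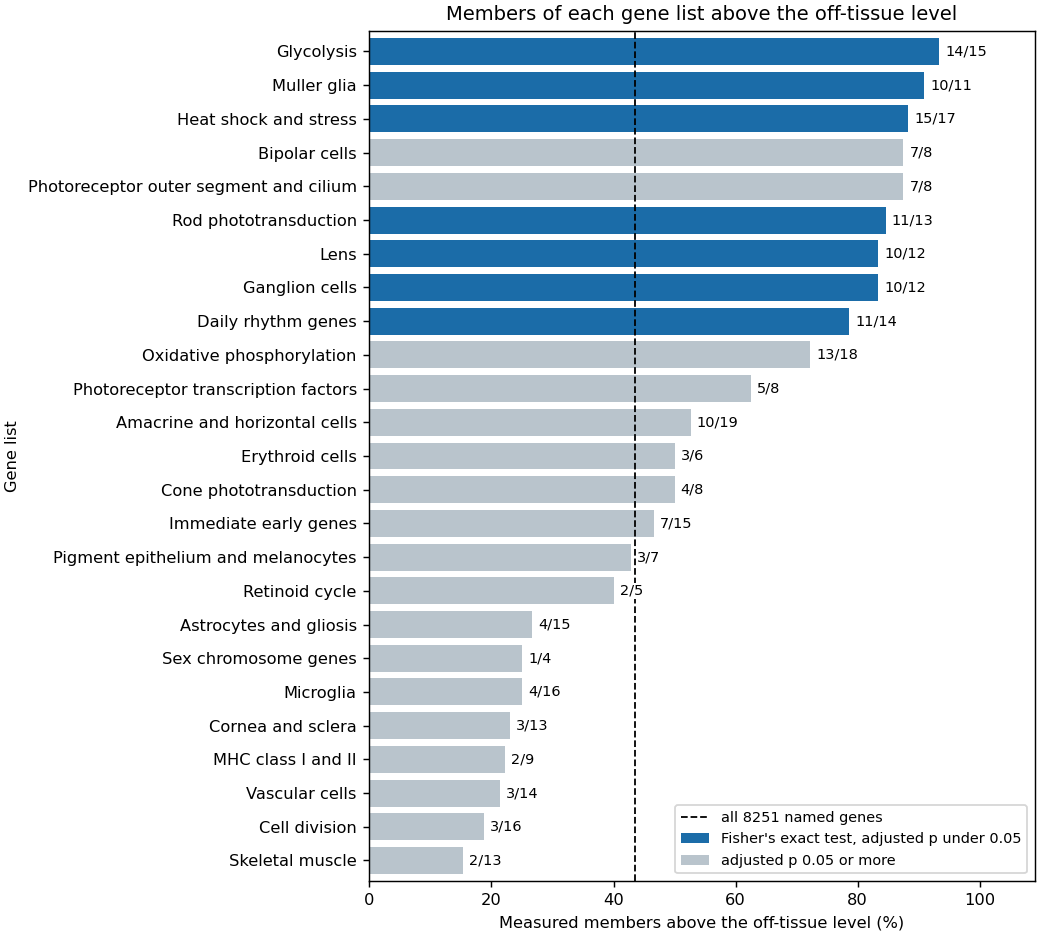
Bars give the percentage of measured members of each gene list (y axis) that were above the off-tissue level (x axis, %), with counts beside the bars and the share of all 8251 genes as a dashed line at 43.5%. Dark bars are the 7 lists with an adjusted p under 0.05 in Fisher's exact test, from 14 of 15 glycolysis genes to 11 of 14 daily rhythm genes.

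The 3 pools were alike for most genes. Among 4523 genes with a mean above the level, the median SD between pools was 0.24 log2 units, or 1.18-fold. With these genes divided by signal into 3 classes of equal size, it was 0.27 in the dimmest, 0.25 in the middle and 0.21 in the brightest class. Across all 8251 genes, which are not independent replicates, Pearson's r was 0.933 between pools 1 and 2, 0.935 between pools 1 and 3 and 0.930 between pools 2 and 3. Spearman's rho was 0.948, 0.946 and 0.943. Among the 4523 genes with a mean above the level, Pearson's r was 0.94, 0.92 and 0.92 for the same pairs. Spearman's rho among them was lower than over all genes, at 0.92, 0.89 and 0.90.

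A 2-fold or wider range over the pools was found for 350 genes (7.74%), a 3-fold range for 61 and a 4-fold range for 23. The widest was Xist, the RNA that coats the inactive X chromosome of female cells, with signals of 954, 37.7 and 1623 in pools 1 to 3, where the pool 2 value lies under that array's level of 219. The acute phase gene Serpina3n had signals of 96.3, 1413 and 944, and the stress-responsive gene Nupr1 had 1443, 2621 and 360. Egr1, an immediate early gene, stood at 900 in pool 1 against 255 and 206, and Alas2 at 1046 in pool 2 against 326 and 228. Low signals in pool 1 were found for Limk1, Hand1, Ankrd33b, Ica1 and Gtf2f2, in pool 2 for Prcc, Arpp19, Eif2ak1, Cyp2c39 and Mir686, and in pool 3 for Lonp1 and Cep250. High signals were found in pool 3 for Pbrm1 and Snrp1c-ps2 and in pool 1 for Tradd. With 1 array per pool these ranges have no test. Other probe sets of Egr1, Prcc, Limk1, Hand1, Ica1, Arpp19, Pbrm1 and Lonp1 differed in range or direction, and the count of 2-fold genes was between 119 and 175 with any 1 pool left out and 2161 with dim genes kept.

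Lens genes differed between pools as a group. In pool 2 all 11 members with a mean above the level were higher than in the mean of the other pools. The alpha crystallin gene Cryaa had signals of 32703, 53133 and 20357 in pools 1 to 3, Crygs 19548, 37184 and 12626, and Crybb2 10778, 16655 and 4427. Crystallins are the structural proteins of lens fibres, and some are also made in retina. The median deviation of the list was 0.86 log2 units in pool 2 (adjusted permutation p = 0.0046) and -0.52 in pool 3 (adjusted permutation p = 0.00828), where 9 of 11 members were lower. The pool 3 call was lost without pool 2, with a deviation of -0.18. Its median SD of 0.54 was wider than the 0.20 of random lists (adjusted permutation p = 0.0023). A second probe set of Crybb2 (632, 838 and 743) was highest in pool 2 but not lowest in pool 3, and one of Cryab was dim and did not share the direction.

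Blood genes with a mean above the level were high in the same pool. Several array controls were also highest there, among them 18S rRNA (337, 878 and 309 in pools 1 to 3). Hba-a1 had signals of 15413, 38145 and 10595 and Hbb-b2 3193, 6437 and 2056. With Alas2, all 3 erythroid members above the level were higher in pool 2, with a median deviation of 1.58 (adjusted permutation p = 0.0046), and all 3 were lower in pool 3, at -1.19 (adjusted permutation p = 0.0092). Without pool 2 the list had fewer than 3 members with a mean above the level, so the pool 3 value was not tested apart from pool 2. The median SD was 0.95 against 0.22 in random lists (adjusted permutation p = 0.00307). The red cell membrane genes Slc4a1 and Epb42 and the carbonic anhydrase gene Car1 were below the level. They went the other way in pool 2, with deviations of -1.03, -1.28 and -0.56. When such dim genes were kept, the deviation of the list fell to 0.38 in pool 2 and was not called.

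Pigment cell genes with a mean above the level were high in pool 3. The melanin synthesis genes Dct (890, 898 and 2993 in pools 1 to 3) and Tyrp1 (268, 165 and 613), the melanosome gene Pmel (590, 721 and 1933) and the transthyretin gene Ttr (395, 332 and 877) were all between 2.43-fold and 3.35-fold over the mean of the other pools. The list deviated by 1.56 log2 units in pool 3 (adjusted permutation p = 0.0046), by -0.84 in pool 2 (adjusted permutation p = 0.0069) and by -0.67 in pool 1 (adjusted permutation p = 0.0217), with 4 of 4 members in the direction each time. Its median SD was 0.94 against 0.25 in random lists (adjusted permutation p = 0.0023). Without pool 3 the mean of Tyrp1 fell below the level, so the list then held only Ttr, Dct and Pmel. Their median SD was 0.18 and their median difference between pools 1 and 2 was 0.013, and neither was called. In pool 2 Ttr was lower than in pool 1 and Pmel was higher. Tyrp1 itself was not called above the level. The members with a mean below the level were mixed. The melanin synthesis gene Tyr was not high in pool 3, at 118, 141 and 105. Slc16a8 (185, 222 and 380) and Mitf (75.3, 152 and 185) were highest there.

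The other 20 lists had no spread or shift past the threshold. Of these, Müller glia came nearest, with a median deviation of -0.38 in pool 3 (adjusted permutation p = 0.0638) and 0.26 in pool 2 (adjusted permutation p = 0.0751). Immediate early genes deviated by 0.32 in pool 1, with 7 of 10 members higher (adjusted permutation p = 0.21). Rod phototransduction, daily rhythm and glycolysis deviated by at most 0.17 in any pool. In all, 7 of 69 tests in 3 lists passed, and 13 had an unadjusted permutation p under 0.05. For lists of genes that vary independently 3.45 would be expected by chance, so the excess is not read as a result.

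**Figure D2:**
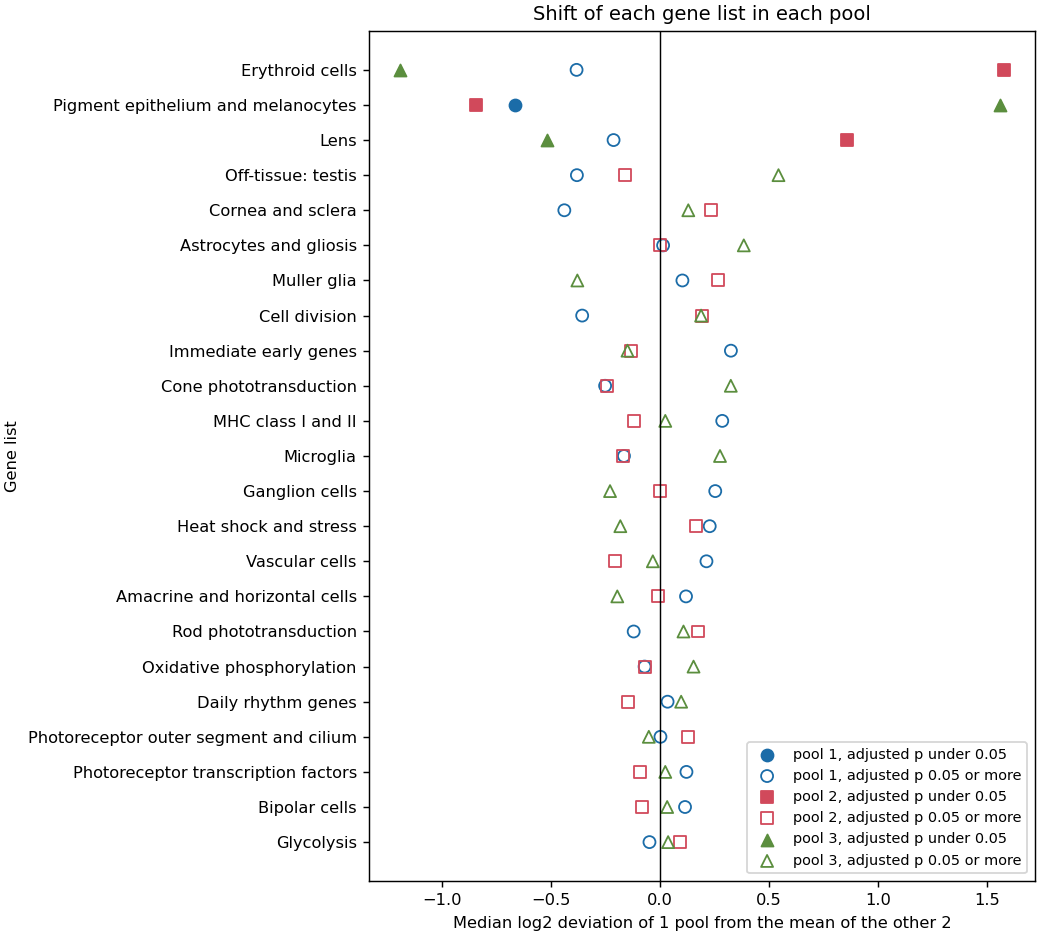
Each symbol is the median log2 deviation of a gene list (y axis) in 1 pool from the mean of the other 2 (x axis, log2 units), with filled symbols for an adjusted permutation p under 0.05. Erythroid and lens genes lie to the right in pool 2 at 1.58 and 0.86, pigment genes in pool 3 at 1.56, and the other lists lie between -0.44 and 0.54.

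**Figure D3:**
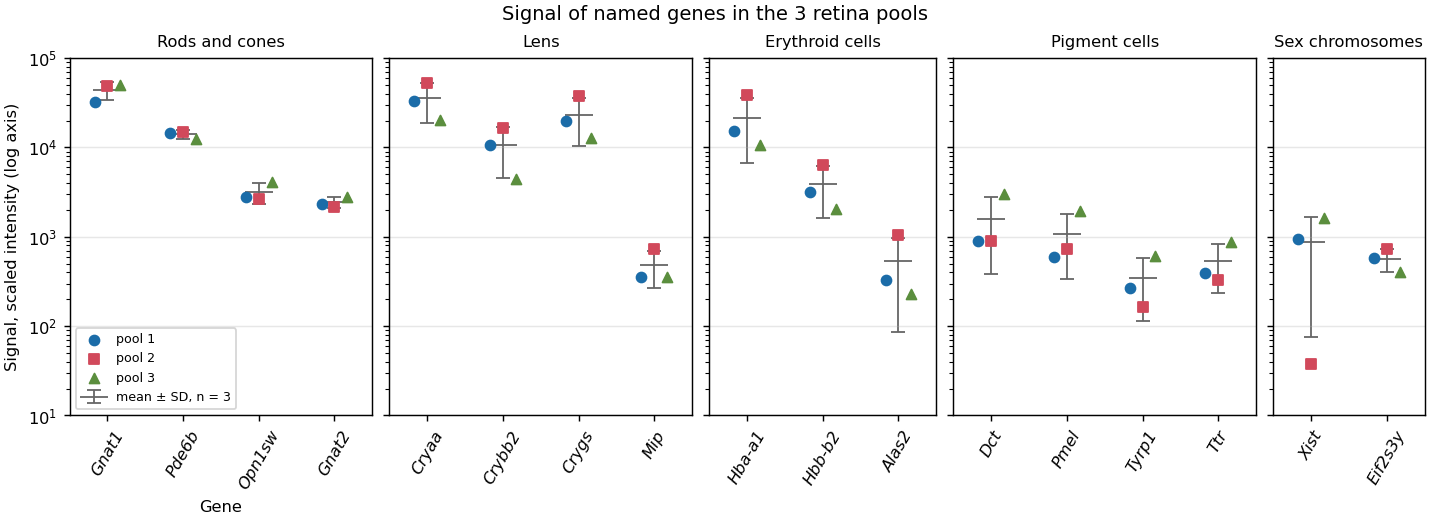
Scaled signal (y axis, log scale) of 17 named genes (x axis) in each of the 3 pools, with a bar for the mean and whiskers for the SD (n = 3). Lens and erythroid genes are highest in pool 2, pigment genes in pool 3, and Xist falls to 37.7 in pool 2.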

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

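The tests of a single level for all arrays and of other variances in limma were chosen after the data were seen. Where no cause is given, the cause was not tested. The count of genes above the level was between 3169 and 5051 under most alternatives, 5703 with bacterial controls as the level, 2474 without pooling the variance in limma, and between 2845 and 4044 with a pool left out. Lists with more members above fell from 7 to 1 at the 75th percentile and 0 with bacterial controls, where more of all other genes are above; elsewhere there were 5 to 8. The daily rhythm call held only with values as deposited, quantile normalization and both other floors. The ganglion cell call held only with these, with the mean over probe sets and without replicate 2. The lens call was lost at the 75th and 95th percentiles, with bacterial controls, without shared-name probe sets, with 1 level for all arrays and without a trend in limma. Müller glia was also lost without replicate 2, and it and heat shock without pooling the variance. A call of fewer members was gained for microglia with quantile normalization and at the 95th percentile, for MHC genes with the mean over probe sets and without shared-name probe sets, and for cornea and sclera and cell division with the mean over probe sets. The median SD was 0.26 at the 75th percentile, 0.28 with bacterial controls and 0.31 without a filter on dim genes, settings that admit dimmer genes; with a pool left out it was between 0.17 and 0.21, from 2 values per gene. Genes with a 2-fold range numbered 829 at the 75th percentile, 1187 with bacterial controls, 2161 without the filter, and between 119 and 175 with a pool left out; 61 had a 3-fold and 1507 a 1.5-fold range. Lists with a wider spread numbered 2 to 4. Called shifts fell from 7 to 3 without the filter and lay between 4 and 8 with a pool left out, and the other settings gave 7 or 8. With a pool left out, the 2 deviations of a list mirror each other. Each such shift is then counted in both pools, so these counts are not like the 7 from 3 pools. The pool 2 lens, pool 2 erythroid and pool 3 pigment shifts kept direction in every setting that gave a value; the lens and pigment ones kept their call, and the erythroid one lost it only without the filter. The pool 2 pigment deviation turned from -0.84 to 0.013 without replicate 3, where pool 1 is the only other pool and Tyrp1 fails the filter. It was -1.42 without replicate 1. Named genes that changed side of the level were Rgr (1.04 log2 units over it at the 75th percentile, 1.66 with bacterial controls), and with bacterial controls Rdh5 (1.02), Lhx1 (1.05), S100b (1.28), Ckm (0.91), Acta1 (0.88) and Mki67 (1.13); with the mean over probe sets Col1a1 (-0.52), Fos (-1.02) and H2-K1 (-0.37); without shared-name probe sets H2-K1 (-0.51) and Cox4i1 (-0.35). Of the other comparisons of single genes with the level, 1013 kept their side and call, 44 lost the call and 35 gained it. No paired analysis was possible because there is 1 group.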

Other observations

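Other genes that stood apart in 1 pool, outside the lists and chosen after their values were seen, were counted among genes with a mean above the level. This filter keeps genes low in 1 pool and bright in 2, and drops genes dim in 2 pools and bright in 1. Low genes outnumbered high ones, which the filter favours, so the imbalance is not read as a result. In pool 3, 40 genes were at least 2-fold below both other pools and 13 were above both, against 21 and 4 in pool 2 and 18 and 12 in pool 1. Among those high in pool 3 was Ptgds, the prostaglandin D2 synthase gene, with signals of 1349, 1728 and 5060 in pools 1 to 3. Among those low in pool 3 were the synaptic vesicle gene Rab3a (540, 585 and 182) and the G protein gene Gnaz (918, 1098 and 316). Both pool 3 values lay under that array's level of 347. Array controls differed too. The actin ratio of 3' to 5' signal was 1.81, 1.60 and 1.24 in pools 1 to 3. The same ratio of Gapdh differed less and was lowest in pool 2, at 0.926, 0.822 and 0.891. The controls that follow were highest in pool 2, the pool of the lens and blood shifts. The 18S rRNA signal was 337, 878 and 309, and the mean signal of the spiked BioB control was 1587, 2590 and 1943. The 5' signal of the spiked Cre control was 32949, 51671 and 42303. The median of the unspiked controls was 14.2 in pool 1 and 38.9 in pool 2, with pool 3 in between.

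For 3 patterns technical explanations were tested. The tests of lens membrane genes and of Y-linked genes were chosen after the results were seen. The design names no factor that differs between the pools, so, apart from the sex of the mice, no biological explanation was tested.

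The lens list was higher in pool 2. Random lists matched on signal had a median deviation of 0.05 log2 units in pool 2, against 0.86 for the list. This argues against a brighter upper end of that array as the whole cause. Under quantile normalization, which gives all arrays 1 distribution, the shift stayed at 0.78 log2 units (adjusted permutation p = 0.00276). That result adds little, because the medians had already been set equal and the random lists matched on signal. Lens tissue carried into the pool remains open and was not decided by the test: Mip, Bfsp1 and Gja3, membrane and cytoskeleton genes of lens fibres, had a median deviation of 1.03 in pool 2, but they are members of the list itself, so the value restates the pattern. Of the 12 lens genes, 10 gave signal above the level in these retina pools. Both lens tissue and retinal expression would give this, so the count does not tell them apart, and retinal crystallin expression is not excluded. Blood genes and array controls were higher in the same pool, which carried-in lens tissue does not cover. A difference in the handling of that array was not tested apart from its scaling.

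The pigment list was higher in pool 3. Scaling would move genes of like signal together. Random lists matched on signal had a median deviation of 0.04 log2 units in pool 3, against 1.56 for the list, which argues against scaling of the whole array. Quantile normalization gave a shift of 1.55 (adjusted permutation p = 0.00276). It adds little, because the medians had already been set equal and the random lists matched on signal. Pigment epithelium or choroid carried into the pool stays open and cannot be told apart from other causes. Rgr, Rdh5 and Stra6, epithelial genes of another list, had a median deviation of 1.29, but none had a mean above the level. Rgr (1.29) and Rdh5 (3.11) were higher in pool 3, while Stra6 was lower there (-1.75). Rdh5 reached 649 and Rgr 436 in pool 3, where the level was 347, and both were under the level in pools 1 and 2, while Stra6 was under it in every pool. Dct and Pmel reached signals of 2993 and 1933 in pool 3. Pool 3 also stood apart for other genes with a mean above the level. It had 197 genes 2-fold apart from pool 1 and 164 from pool 2, against 115 between pools 1 and 2. A difference in the handling of that array was not tested apart from its scaling.

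Xist was lower in pool 2, at 37.7 against an array level of 219, than in pools 1 and 3, at 954 and 1623. The labels give no sex for the mice. Fewer female mice in that pool stays open: 3 Y-linked genes and the probe set shared by Zfy1 and Zfy2 had a median deviation of 1.12 in pool 2, and all 4 were higher there. Only Eif2s3y of these was called above the level, and its deviation was 0.61, or 1.53-fold, so the median rests on dim genes and does not decide. The probe set of Eif2s3y is of the shared-name kind, so its signal may not come from that gene alone. A failed probe set cannot be told apart from this, because the array has 0 other probe sets that name Xist.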
